A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

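Poly(A) RNA of Saccharomyces cerevisiae strain W303-1A was compared between wild-type cells (2 libraries) and cells lacking both the decapping enzyme Dcp2 and the cytoplasmic 5′ to 3′ exonuclease Xrn1 (3 libraries, genotype dcp2D::HIS3 xrn1D::kanMX). Per the labels' protocols, cells grew in rich medium at 30 °C to an OD600 of 0.3, and an adaptor was ligated to RNA that carries a 5′ monophosphate, so a capped message is not captured. The ligated RNA was copied from its poly(A) tail, amplified for 10 cycles and cut with MmeI 20 or 21 nt into the sequence before a further amplification. Each read therefore marks the 5′ end of a polyadenylated RNA fragment.

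The deposited values are read counts, whole numbers at each nucleotide of each transcript, given as 1 profile per transcript and library, and no normalization was applied to them by the authors as far as the values show. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 to the genome build R64. How many mismatches were allowed, and what was done with reads that matched several places, is not stated. The profiles cover 6603 transcripts, of which 5916 are annotated protein-coding genes in the R64 reference. The other 687 were kept out of the main tests. Where same-strand transcripts overlap, the same reads stand in both profiles (equal at every base in 48 of the 48 pairs that could be checked). Positions whose 20-mer occurs more than once in the genome make up 3.15% of the profiles and hold at most 0.0224% of each library's reads. Genes with close copies were therefore counted mostly outside such positions.

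The profiles of 4995 genes are longer than the annotated gene span, because they include untranslated regions whose lengths the deposited data do not give. The lengths on each side were inferred by sliding the profile along the genome and taking the placement at which the bases around the ends best matched the base preference seen in the genes with no extra length. That preference was then re-estimated with the genes it had placed added, and the placement was repeated. A placement was accepted where its log-likelihood exceeded that of the next by more than 7, a limit set after the data had been seen, which placed 3368 genes. Genes without extra length, 919 searched over a hidden shift of up to 75 nt on either side, gave 159 accepted placements, 99.4% of them at the true start. The same genes had helped to set the base preference, so this check is not independent of it. With ends moved to random positions 6.68% of genes were accepted. Positions relative to the start codon, stop codon, introns and untranslated regions use only placed genes and the 920 genes with no extra length. Coordinates are R64, counted from 1.

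Total reads were 142023128 and 37033689 in wild-type replicates 1 and 2, and 11692191, 89080390 and 79557271 in mutant replicates 1, 2 and 3. The libraries have no molecular identifiers, and reads at single positions pile up around a first mode of 33.4, 28.1, 72.9, 636 and 981 reads in the same order. Dividing each library's reads in annotated genes by that mode estimates 4221743, 1309127, 157849, 137718 and 79608 ligated fragments. Tests in estimated fragments divided position by position, rounded to at least 1, and left out positions at or under the mode divided by 4. Summed, these came to 4295038, 1332851, 174680, 140784 and 79392. These estimates were devised after the data had been seen. Detection floors were set at 3 such fragments, which correspond to 0.716 and 2.20 CPM in the wild-type libraries and to 18.8, 22.3 and 38.5 CPM in the mutant libraries. Floors cover counting error only. A second mode lay at 66.8 and 56.2 reads in the wild-type libraries and at 1272 and 1961 reads in mutant replicates 2 and 3. Median reads per position with reads were 56, 45, 73, 1185 and 1709 in the order above. Whether the first mode marks 1 fragment was not tested, so fragment numbers, floors and fold bounds may be off.

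Reads were summed per gene and compared with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM scaling, filterByExpr), with Benjamini-Hochberg adjustment at 0.05, all 5 libraries, no covariate, two-sided. The SE given for a gene is its absolute log2 fold change divided by the square root of the F statistic. It is not a separately estimated standard error. Every adjusted p of a gene comes from the edgeR test. CPM values of genes are relative to the library total after TMM scaling (factors 0.978 to 1.04), except in the correlations across genes, where they were not scaled. A change is therefore one in a gene's share of the scaled total of captured ends. Among 32 gene lists written before the data were examined, those with at least 3 measured members were tested with camera (limma 3.58.1, preset correlation 0.01) and again with an estimated correlation, leaving out DCP2, XRN1 and HIS3. Sites were compared relative to their gene with edgeR's diffSpliceDGE, for nucleotides with at least 20 reads in all and at least 5 in each of 2 libraries. Region shares, the first and last of 3 equal parts of the coding sequence, codon position, ends near start and stop codons, concentration and base composition were compared with an exact permutation test over the 10 assignments of the 5 libraries, two-sided, whose smallest p is 0.1. Codon position and the 3 parts used genes with at least 50 coding reads in every library, each gene weighted equally, and codon position left out the first and last 60 nt. The window before the stop codon was 18 to 16 nt upstream of its first base, that before the start codon 14 to 12 nt, each against 60 to 31 nt upstream, in genes with at least 10 reads in those 60 nt in every library. With first modes of 72.9, 636 and 981 reads in the mutant libraries, 1 estimated fragment there can pass the limit of 50 or 10 reads. The mutant value of a single gene can therefore rest on 1 fragment.

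The genes named are, by a rule fixed before the data were examined, DCP2, XRN1 and HIS3, the 8 with the largest fold in each direction (adjusted p under 0.05, mean of at least 20 CPM, groups not overlapping), the 3 members of each list with the smallest p (2 where under 6 were measured), HAC1 and CBP1, and the 6 sites with the largest gain and loss. Not every gene that the rule takes is named in the text. Features outside that rule are said to be chosen after their values were seen. The tests, windows, lists and the first set of alternatives were fixed before the data were examined. The fragment estimates, all settings built on them, the fit on all transcripts, the use of genes without extra length and the lists under distinct positions were added afterwards.

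Alternatives were other scalings, filters and tests (DESeq2 1.42.0 among them), each library left out in turn, the replicate number as a factor, distinct end positions, coding reads alone, other weights and windows, and estimated fragments. Labels do not say whether replicates are separate cultures, so p-values may measure technical spread. The gene test, the site test, codon position and the window before the stop codon were checked on simulated counts. The other tests were not checked in this way. With 200 genes changed among 5475, the gene test called 0%, 36%, 52% and 42% of those changed 2, 4, 8 and 16-fold, with 2 unchanged genes called. The site test on 426347 sites recovered 0% at 4-fold, 0% at 16-fold, 24% at 64-fold and 48% at 1024-fold, with 201 unchanged sites called; the 2 larger folds were added after smaller ones had recovered none. A further simulation drew every library's number of fragments from the wild-type profile with no change and gave 0 genes called by edgeR of 5516 (226 at an unadjusted p under 0.05). Its libraries differed by sampling alone, without spread between replicates, so it does not show how many calls in the real libraries are false. Other versions were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.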

Results

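The data map, in budding yeast, the ends of polyadenylated RNA that carry a 5′ monophosphate, in 2 libraries from wild-type cells and 3 from cells without Dcp2, which removes the cap, and Xrn1, which degrades uncapped RNA from its 5′ end. Comparing the strains asks which messages, and which places in a message, hold uncapped ends when the main decapping and 5′ to 3′ decay enzymes are missing. Totals ranged from 11692191 to 142023128 reads per library, on 1396140 and 561267 positions in the wild-type libraries and on 125492, 63980 and 48595 positions in the mutant libraries. The mutant reads rest on about 79608 to 157849 estimated fragments per library, the wild-type reads on 1309127 and 4221743. Across genes, log2(CPM + 1) correlated with a Pearson r of 0.991 between the wild-type libraries, 0.804 to 0.855 between mutant libraries and 0.749 to 0.838 across strains (genes are not independent replicates).

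The genes altered in the strain were looked at first. XRN1 (chromosome VII, 175527 to 180113, minus strand) had 55307 and 15386 reads in its coding sequence in the wild-type libraries and 0 in each of the 3 mutant libraries. Over its whole transcript it had 399.98 and 408 CPM in wild type and 1.72, 6.38 and 0 CPM in the mutant (adjusted p 0.0614). DCP2 (chromosome XIV, 402652 to 405564, minus strand) had 17207 and 3404 wild-type reads in the 1831 nt from its start codon to position 403734, and 0 in each mutant library. Downstream of that position the mutant libraries held 4124, 49660 and 52908 reads, so the DCP2 total did not differ (log2 fold change 0.40, SE 0.31, adjusted p 0.450), and that downstream part does not check the deletion. The boundary at 403734 was taken from the mutant reads themselves. HIS3 (chromosome XV, 721946 to 722608, plus strand), the marker used to replace DCP2, had 28.9 and 29.5 CPM in wild type and 146, 119 and 66.4 CPM in the mutant (log2 fold change 1.92, SE 0.48, adjusted p 0.0507). The profiles do not tell reads of the marker from those of the strain's own HIS3 locus, so this value does not check the replacement.

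Of 5533 genes tested, 498 held a larger share of the TMM-scaled ends in the mutant and 432 a smaller one (adjusted p under the threshold, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HAC1, which encodes the transcription factor of the unfolded protein response and is spliced outside the nucleus by the endonuclease Ire1 and tRNA ligase, rose 26.6-fold (log2 fold change 4.73, SE 0.10, adjusted p 0.000124). It went from 438 ± 4.38 CPM (SD, n = 2) to 11650 ± 489 CPM (SD, n = 3). SED1, a cell wall protein (chromosome IV, 600793 to 601809, plus strand), rose 71.8-fold to 29242 ± 4750 CPM (SD, n = 3), from 407 ± 59.9 CPM (SD, n = 2). Lists of messages for ribosomal proteins, respiration, glycolysis, the cell wall and the general stress response were called higher with a preset correlation, and those for ribosome biogenesis, cell cycle regulators and the pheromone response lower. None of these calls held with an estimated correlation (smallest adjusted p 0.133). At least 4-fold differences were found for 208 of the 498 genes that rose and for 123 of the 407 that fell from a wild-type mean above the mutant floor.

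Among the 8 genes with the largest fitted rise, 3 had no reads in either wild-type library. Their mutant means were set against the wild-type floor of 1.46 CPM (mean over the group), with no allowance for counting error in the mutant. YNR064C (25.05, 30.8 and 107 CPM in the mutant libraries, adjusted p 0.0190) lay 37.3-fold above that floor, SPG4 (28.1, 36.4 and 80.0 CPM, adjusted p 0.0171) 33.03-fold and DPA10 (6.37, 77.4 and 53.8 CPM, adjusted p 0.0311) 31.5-fold. These values rest on 5, 4 and 8 mutant fragments for YNR064C, 5, 5 and 6 for SPG4, and 1, 11 and 4 for DPA10. DPA10 lay under the floor of mutant replicate 1 (18.8 CPM), and none of the 3 was tested in estimated fragments. The small heat-shock protein genes HSP12 (chromosome VI, 107256 to 107585, plus strand) and HSP26 (chromosome II, 382030 to 382674, plus strand) rose by log2 fold changes of 8.93 (SE 2.19, adjusted p 0.0497) and 7.01 (SE 1.24, adjusted p 0.0234). HSP12 had 0 and 3.08 CPM in wild type and 608, 731 and 740 CPM in the mutant. The cell wall mannoprotein gene HPF1 rose by 6.45 (SE 1.06, adjusted p 0.0196) and CPP3 by 5.99 (SE 1.21, adjusted p 0.0315), and SED1 by 6.17 (SE 0.23, adjusted p 0.000905). Wild-type levels of HSP26, HPF1 and CPP3 lay under or near the floor, from 0.574 to 3.13 CPM.

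The largest fitted falls were of FRE4, a reductase for iron uptake (chromosome XIV, 739951 to 742110, plus strand), and CMR1 (chromosome IV, 174918 to 176486, plus strand), a DNA-binding protein, neither of which had a read in any mutant library, so that their place before the other genes is not shown. FRE4 had 266 and 232 CPM in wild type and was at least 9.37-fold lower in the mutant, set against its mean floor of 26.5 CPM (adjusted p 0.00590). CMR1 had 67.2 and 47.9 CPM and was at least 2.17-fold lower (adjusted p 0.0274). TRM44 (log2 fold change -3.94, SE 0.70, adjusted p 0.0236), the mating-type endonuclease gene HO (-3.83, SE 0.60, adjusted p 0.0185), and HST4 (-3.83, SE 0.62, adjusted p 0.0190) followed. Next came RRN11 (-3.70, SE 0.76, adjusted p 0.0318), the centromere protector gene SGO1 (-3.66, SE 0.69, adjusted p 0.0270) and MSA1 (-3.58, SE 0.32, adjusted p 0.00657). Mutant means of TRM44, HO and HST4 lay under the mutant floor, at 14.9, 16.4 and 14.7 CPM. Their place before RRN11, SGO1 and MSA1 is therefore not shown either. Of the 432 genes that fell, 29 were at 0 in all mutant libraries. A wild-type mean under the mutant floor was found for 25 of these, so 407 were lower from a level that mutant libraries could have shown.

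The groups' values did not overlap in 3174 tested genes (57.4%). Exchangeable libraries would give 20%. The mutant libraries rest on far fewer fragments and agree less with each other. So 20% is not a measured chance level for these data, and no excess is read from it. The numbers called depended on single libraries: 58 higher and 21 lower without wild-type replicate 1, 67 and 32 without wild-type replicate 2, 273 and 278 without mutant replicate 2, and 556 and 734 without mutant replicate 1. Of the 93 named genes called, 20 were called whichever library was left out, among them ALD4, CIT2, COR1, CYT1, FRE4, GAS5, GPH1, HAC1, ILV5, NOP4, PDC1, PGI1, RPL10, RPL26B, RPS29B, SCW4, SED1, SER3 and YGP1. With distinct end positions counted in place of reads, HXT3, TEF4, ILV5, PHO84 and PRT1, called lower in reads, had log2 fold changes of 0.38, 1.54, 1.84, 0.93 and 0.059. That count is bounded by the length of the gene, and ILV5 had 29699 and 9510 estimated fragments in wild type. In estimated fragments all 5 stayed lower (-0.99, -0.76, -0.93, -0.97 and -1.02, the largest adjusted p 0.00107).

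Of the 30 lists with enough members, 9 were higher and 4 lower by camera with a preset correlation. None held with an estimated correlation, where the smallest adjusted p was 0.133 and 8 lists had an unadjusted p under 0.05. Each list's direction therefore rests on its members' own tests. Numbers in parentheses after a gene are its log2 fold change and SE. The general stress response list, genes induced by many stresses, had 12 of 27 members higher and 0 lower (21 and 0 adjusted over the list alone; camera adjusted p 1.24e-10, with an estimated correlation adjusted p 0.147). The members ALD4 (46.7 ± 4.93 to 831 ± 79.9 CPM, SD, n = 2 and 3), GPH1, glycogen phosphorylase (14.4 ± 3.45 to 368 ± 48.3 CPM), and YGP1 (13.01 ± 1.86 to 242 ± 32.1 CPM) rose by log2 fold changes of 4.15, 4.67 and 4.22. Cell wall genes rose in 15 of 20 cases and fell in 0 (17 and 0 over the list alone; adjusted p 1.89e-09, with an estimated correlation adjusted p 0.147). Smallest p-values went to SED1, the glucanase-like SCW4 (3.22, SE 0.15) and the glucanosyltransferase GAS5 (2.51, SE 0.15). Among chaperones 9 of 27 rose and 0 fell (14 and 1 over the list alone; adjusted p 0.000126, with an estimated correlation adjusted p 0.147). HSP104 (1.59, SE 0.15), CPR6 (1.21, SE 0.17) and HSP42 (1.75, SE 0.28) were among them.

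The respiratory chain and ATP synthase list had 21 of 35 members higher and 0 lower (23 and 0 adjusted over the list alone; camera adjusted p 3.02e-10, with an estimated correlation adjusted p 0.133). The complex III genes COR1 and CYT1 rose by 2.21 (SE 0.17, adjusted p 0.00464) and 2.17 (SE 0.19, adjusted p 0.00603). The cytochrome oxidase gene COX9 rose by 2.99 (SE 0.39, adjusted p 0.0116). In glycolysis and fermentation 11 of 20 rose and 0 fell (14 and 0 over the list alone; adjusted p 1.87e-06, with an estimated correlation adjusted p 0.176). PDC1, pyruvate decarboxylase (1.99, SE 0.13), PGI1 (1.97, SE 0.17) and GPM1 (1.15, SE 0.11) were among these. In the tricarboxylic acid cycle 9 of 15 rose and 1 fell (10 and 1 over the list alone; adjusted p 0.000168, with an estimated correlation adjusted p 0.224). The mitochondrial citrate synthase gene CIT1 rose by 2.03 (SE 0.24) and IDH2 by 1.34 (SE 0.14). CIT2, the peroxisomal citrate synthase, was the member that fell (-1.61, SE 0.17). Ergosterol biosynthesis had 4 of 23 higher and 0 lower (6 and 1 over the list alone; adjusted p 0.0165, with an estimated correlation adjusted p 0.372). ERG13 (1.92, SE 0.24), ERG20 (1.42, SE 0.22) and ERG6 (1.17, SE 0.19) had the smallest p there.

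Large-subunit protein genes had 33 of 82 members higher and 2 lower (39 and 3 adjusted over the list alone; camera adjusted p 5.21e-10, with an estimated correlation adjusted p 0.224). RPL10 rose by 2.28 (SE 0.15, adjusted p 0.00434). RPL26B (2.13, SE 0.16, adjusted p 0.00457) and RPL28 (1.28, SE 0.12, adjusted p 0.00606) came next by p. Small-subunit protein genes had 29 of 56 higher and 0 lower (36 and 1 over the list alone; adjusted p 5.21e-10, with an estimated correlation adjusted p 0.147). Among them were RPS29B (3.56, SE 0.22, adjusted p 0.00434), RPS26A (2.63, SE 0.26) and RPS26B (2.43, SE 0.28). Of the ribosome biogenesis list 0 of 57 rose and 13 fell (1 and 16 over the list alone; adjusted p 0.00202, with an estimated correlation adjusted p 0.147). NOP4 (-1.89, SE 0.19, adjusted p 0.00752), UTP22 (-1.59, SE 0.26) and DBP3 (-1.48, SE 0.25) had the smallest p of these. Cyclins and cell cycle regulators had 0 of 21 higher and 4 lower (0 and 5 over the list alone; adjusted p 0.00202, with an estimated correlation adjusted p 0.176). The polo kinase gene CDC5 fell by 3.02 (SE 0.54) and the G1 cyclin gene CLN3 by 1.08 (SE 0.15). In the haploid pheromone response 0 of 13 rose and 5 fell (0 and 5 over the list alone; adjusted p 0.0165, with an estimated correlation adjusted p 0.212). STE4 (-1.54, SE 0.17), STE12 (-1.01, SE 0.17) and KAR4 (-2.48, SE 0.51) were 3 of them.

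The hexose transporter list was lower (adjusted p 0.0324, with an estimated correlation adjusted p 0.224), with 0 of 9 higher and 2 lower (1 and 4 over the list alone). Its median was -1.09 as fitted and 0 with undetected members at their bound. The called member HXT7 lay under the floor in both strains, as did HXT14 (adjusted p 0.0528). HXT3 fell by 1.09 on the log2 scale (SE 0.18, adjusted p 0.0205). In estimated fragments the list had an adjusted p of 0.374, and the ergosterol list lost its call without mutant replicate 2.

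**Figure D1:**
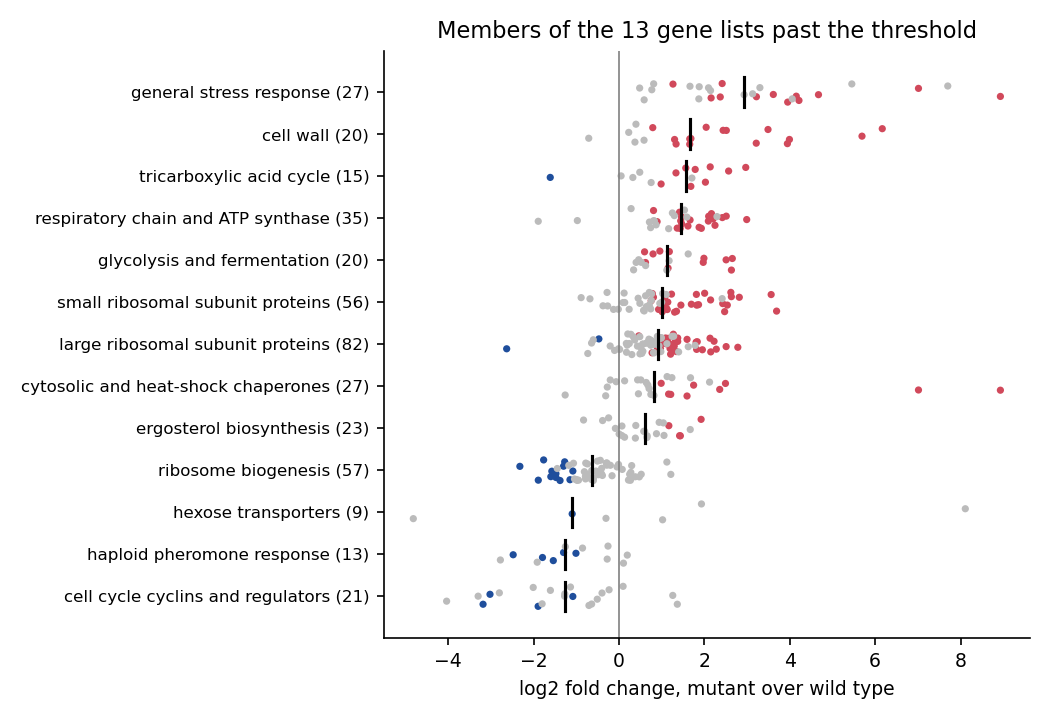
Log2 fold change, mutant over wild type (horizontal axis), of each member of the 13 lists past the threshold (vertical axis). Points are genes, red or blue where the gene was higher or lower at the adjusted p threshold and grey where it was not, the black tick is the list's median, and genes at 0 in a whole group are not drawn; the stress response median is 2.93 and that of the cell cycle list -1.27.

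The other 17 lists tested did not pass. Messages with reported endonuclease cleavage or Edc3 control had 3 of 8 higher and 0 lower (4 and 1 adjusted over the list alone; camera adjusted p 0.0724). HAC1 and RPS28B (0.78, SE 0.16) were among them. Amino acid biosynthesis had 8 of 50 higher and 3 lower (8 and 4 over the list alone; adjusted p 0.102). SER3 was 8.02-fold higher, and TRP5 (1.24, SE 0.17) and ILV5 (-1.01, SE 0.09) also passed. Mitochondrial ribosomal proteins had 1 of 69 higher, MRPS18 (2.03, SE 0.37), and 7 lower, RSM25 (-2.08, SE 0.31) and MRPL4 (-2.16, SE 0.42) among them (0 and 0 over the list alone; adjusted p 0.114). Oxidative stress genes had 3 of 17 higher and 0 lower (6 and 0 over the list alone; adjusted p 0.121). They were GLR1 (1.24), GRX1 (2.08) and PRX1 (1.65). The phosphate regulon had 1 of 12 higher, PHO89 (2.25), and 3 lower, VTC3 (-1.58) and PHO84 (-1.03) among them (1 and 4 over the list alone; adjusted p 0.121).

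Nonsense-mediated and no-go decay factors had 1 of 9 higher, ASC1 (0.95, SE 0.12), and 2 lower, HEL2 (-2.03, SE 0.30) and UPF3 (-1.01, SE 0.19). Adjusted over the list alone the counts were 1 and 4 (camera adjusted p 0.130). Deadenylation and 3′ to 5′ decay genes had 1 of 27 higher, PAB1 (1.14, SE 0.17), and 5 lower, PAN2 (-2.10, SE 0.22) and CDC39 (-1.30, SE 0.18) among them (1 and 7 over the list alone; adjusted p 0.191). Decapping and 5′ to 3′ decay genes had 2 of 19 higher, the cap scavengers DCS1 (1.66, SE 0.33) and DCS2 (2.11, SE 0.49), and 1 lower, LSM4 (-1.58, SE 0.30). Over the list alone the counts were 2 and 1 (adjusted p 0.580). Of reported nonsense-mediated decay substrates CPA1 was the 1 of 7 that rose (1.43, SE 0.20) and 0 fell (1 and 0 over the list alone; list adjusted p 0.603). EST1 (1.86, adjusted p 0.127) and EST3 (-0.52, adjusted p 0.422) did not pass.

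In the unfolded protein response and ER folding list, which does not hold HAC1, PDI1 (1.19, SE 0.19) and ERO1 (1.55, SE 0.26) were the 2 of 15 that rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p 0.273). KAR2 had a log2 fold change of 0.88 (SE 0.30, adjusted p 0.105). Translation factors had 5 of 36 higher, YEF3 (1.13) among them, and 2 lower, TEF4 (-0.85) and PRT1 (-1.08). Over the list alone 5 and 2 passed (adjusted p 0.374). Proteasome genes had 3 of 33 higher, RPT6 (1.59) and PRE7 (1.19) among them, and 2 lower, PRE2 (-1.23) among them (3 and 2 over the list alone; adjusted p 0.553). Of the iron regulon ARN2 (3.12) and HMX1 (1.68) rose and FRE1 fell by 1.37, out of 17 (2 and 1 over the list alone; adjusted p 0.762). HHF2 (1.61) was the 1 of 10 histone genes that rose and 0 fell (1 and 0 over the list alone; adjusted p 0.374). HTZ1 (adjusted p 0.247) and HHO1 (adjusted p 0.249) did not pass.

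Mating-type a-specific genes had 1 of 7 higher, AGA2 (3.40, SE 0.43), and 1 lower, STE6 (-2.69, SE 0.45), with 1 and 1 adjusted over the list alone (camera adjusted p 0.383). STE2 had an adjusted p of 0.122. SAG1, the 1 alpha-specific gene measured, had 62.9 and 75.8 CPM in wild type and 427, 359 and 356 CPM in the mutant (2.46, SE 0.23, adjusted p 0.00682). Meiosis and sporulation genes had 0 of 18 called in either direction (0 and 0 over the list alone; adjusted p 0.630). DIT2, SMK1 and SPO11 lay under the mutant floor in both strains, as did TIR1. The seripauperin and cell wall mannoprotein list had 0 of 7 called (0 and 0 over the list alone; adjusted p 0.642), with TIR4 at an adjusted p of 0.234 and DAN4 at 0.555. The list's median was positive and its mean and camera direction negative, as for meiosis and sporulation. Subtelomeric helicases had 0 of 8 members measured, which does not show that they hold no ends. CBP1, whose message has been reported to be cut by an endonuclease, had 54.4 and 39.1 CPM in wild type and 55.1, 105 and 130 CPM in the mutant (log2 fold change 1.05, SE 0.50, adjusted p 0.222).

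HAC1 ends in the mutant gathered in the first 5 nt after the splice sites that Ire1 cuts. The gene runs from 75179 to 76147 on the plus strand of chromosome VI, with its intron at 75840 to 76091. In the mutant libraries 30.7 ± 0.382% of HAC1 reads (SD, n = 3) began in the first 5 nt of the intron (chromosome VI, 75840 to 75844), against 2.57 ± 0.576% in wild type (SD, n = 2). A further 37.8 ± 3.91% began in the first 5 nt of exon 2 (76092 to 76096), against 1.32 ± 0.195% in wild type. The most used positions were 76093, with 21.9% of the mutant reads, and 75840 and 75841, with 15.04% and 14.7%. The first base of exon 2 itself, 76092, held 1.51%. Which enzyme left these ends was not tested. The shares in the 3′ untranslated region (18.7% in the mutant, 63.7% in wild type) and the coding part of exon 1 (5.41% and 19.04%) were lower only relative to the gene's total. In CPM both rose, from 279 ± 22.5 to 2187 ± 374 and from 83.5 ± 11.97 to 634 ± 175 (SD, n = 2 and 3). The shares at the intron and exon 2 starts separated the strains without overlap (exact permutation p 0.1, the smallest possible). Parts and positions of HAC1 were chosen after its profile was seen.

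**Figure D2:**
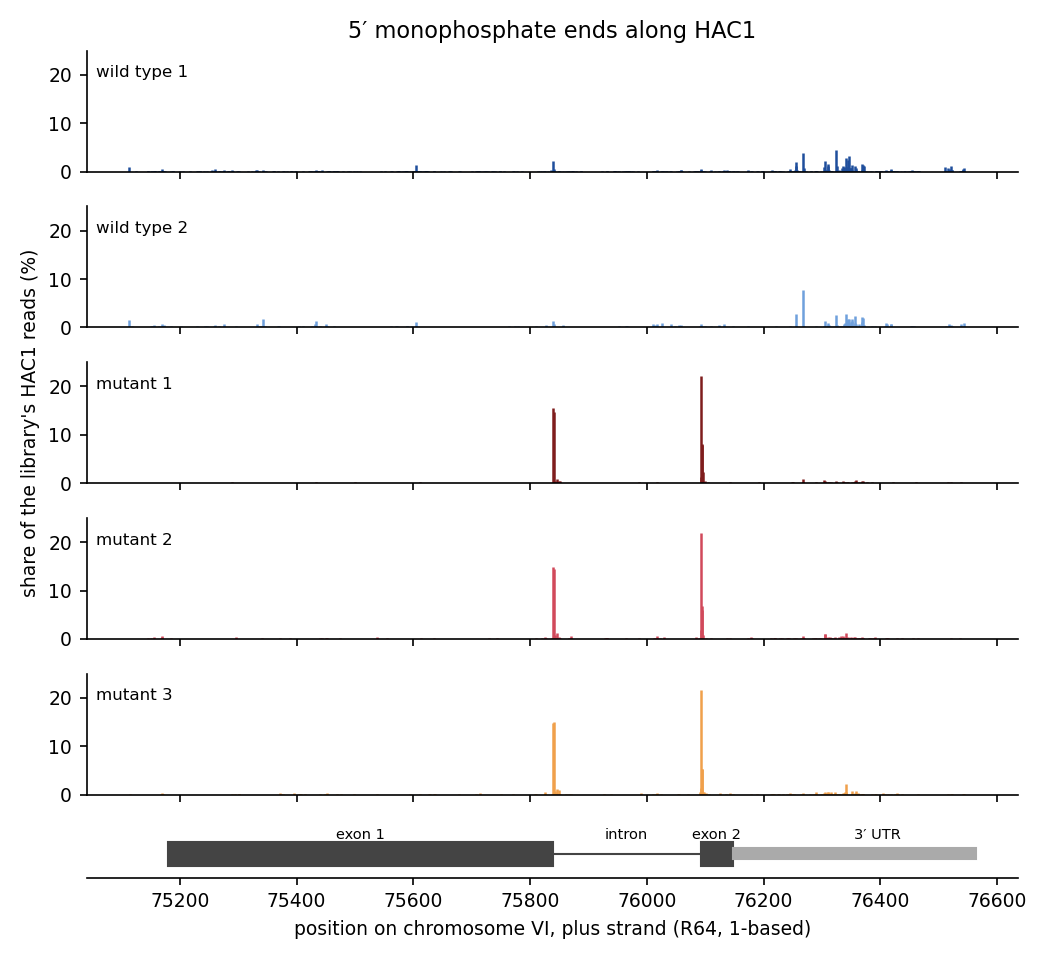
Share of each library's HAC1 reads (percent, vertical axis) that begin at each position of chromosome VI (horizontal axis, R64), 1 panel per library, with exons, intron and coding sequence marked. In the 3 mutant libraries the tallest bars stand at the first bases of the intron and of exon 2.

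Within coding sequences, wild-type ends followed the reading frame and mutant ends did so less. Over 3158 genes, 41.7 ± 0.825% of wild-type ends (SD, n = 2) lay at codon position 1, 39.3 ± 1.88% at position 2 and 19.1 ± 1.06% at position 3. In the mutant the shares were 32.2 ± 0.507%, 36.9 ± 0.220% and 30.8 ± 0.567% (SD, n = 3). All 3 comparisons gave an exact permutation p of 0.1, the smallest possible with 10 assignments. With each site counted once, position 2 no longer separated the strains (permutation p 0.8).

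**Figure D3:**
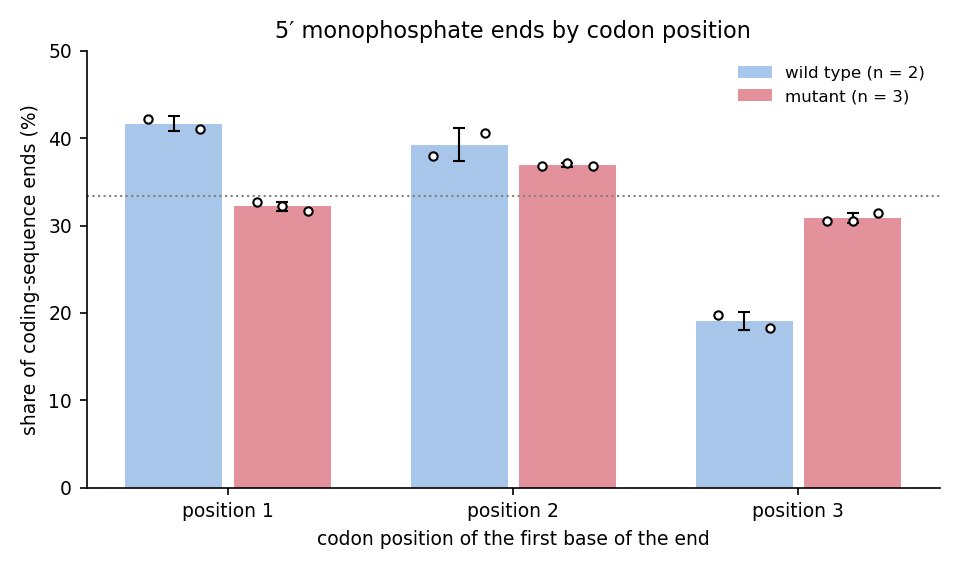
Share of coding ends (percent, vertical axis) at each codon position (horizontal axis) in wild type and mutant, with bars for means, error bars for SD, points for libraries and a dotted line at equal use. The wild-type libraries sit at 42.2% and 41.1% at position 1 and the mutant libraries between 31.7% and 32.7%.

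Ahead of the stop codon, at the distance of the upstream edge of a ribosome waiting on it, wild-type ends were in excess and mutant ends were not. The density 18 to 16 nt upstream of the stop codon was 2.445 ± 0.353 times that 60 to 31 nt upstream in wild type (SD, n = 2) and 0.794 ± 0.179 times in the mutant (SD, n = 3), over 424 genes (exact permutation p 0.1, the smallest possible). At 17 nt alone the ratios were 3.70 and 1.01. Ahead of the start codon the ratio was 1.63 ± 0.132 in wild type and 0.819 ± 0.348 in the mutant over 71 genes (exact permutation p 0.2). At 13 nt alone the order was the other way round, 0.510 against 0.822.

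**Figure D4:**
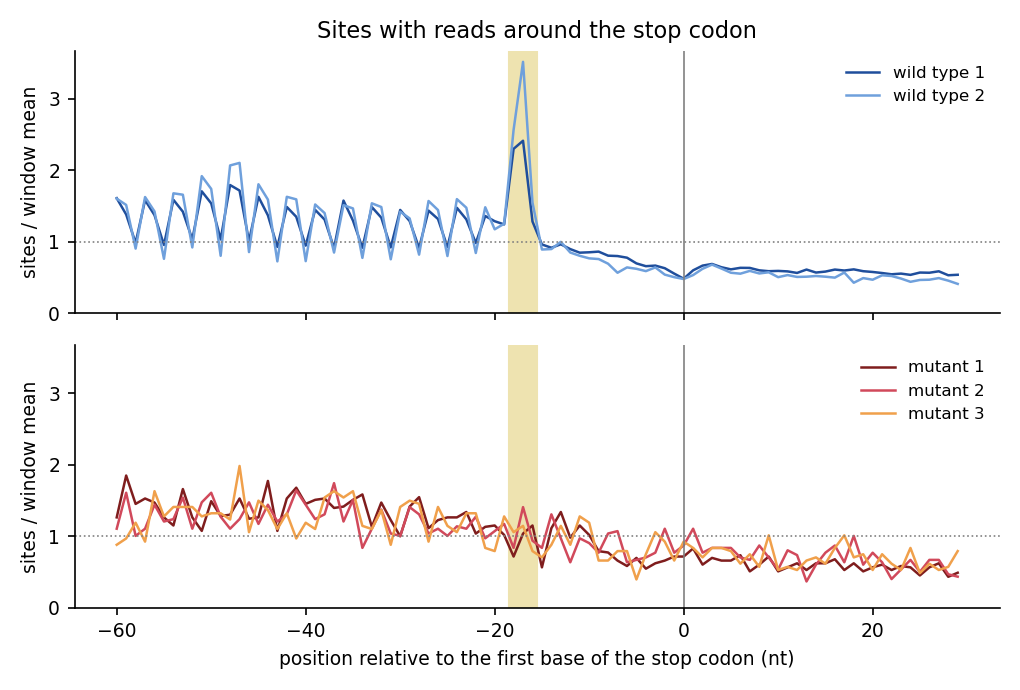
Sites with reads, each counted once and divided by the mean of the window (vertical axis), from 60 nt upstream to 29 nt downstream of the stop codon (horizontal axis, nt), 1 line per library. The shaded window at 18 to 16 nt upstream holds a peak in the wild-type libraries and none in the mutant libraries. Over the 3132 genes drawn, the mean there was 1.69 times that of 60 to 31 nt upstream in wild type and 0.758 times in the mutant.

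Mutant ends lay nearer the 5′ end of coding sequences. The first of 3 equal parts of the coding sequence held 15.1 ± 0.119% of coding ends in wild type and 21.4 ± 0.427% in the mutant. The last part held 55.0 ± 0.108% and 46.7 ± 0.3797% (3215 genes; exact permutation p 0.1 for both, the smallest possible). Of all reads in placed genes, 5′ untranslated regions held 2.13 ± 0.0247% in wild type and 3.99 ± 0.440% in the mutant. Coding sequences held 94.3 ± 0.109% and 90.9 ± 0.892%, and 3′ untranslated regions 3.61 ± 0.0840% and 5.10 ± 0.459% (3267 genes; exact permutation p 0.1). With each gene weighted equally these differences were smaller, 2.63% against 3.01% upstream of the start codon and 5.01% against 5.37% downstream of the stop codon (permutation p 0.2).

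At the first base of the ends G was less frequent in the mutant (22.5 ± 0.494% to 16.8 ± 0.235%) and T more (23.1 ± 0.782% to 30.2 ± 1.01%). A went from 35.4 ± 0.748% to 32.5 ± 0.727% (exact permutation p 0.1 each). Each site was counted once per library, and sites summed over the 5 libraries numbered 1882299. At the base before the end A was more frequent (33.2 ± 0.0855% to 36.9 ± 0.856%) and T less (28.98 ± 0.0412% to 25.8 ± 0.398%), again with an exact permutation p of 0.1. C at the first base (19.003% against 20.5%, permutation p 0.5), C before the end (20.3% against 20.0%, permutation p 0.6) and G before the end (17.5% against 17.3%, permutation p 0.4) differed by less than the larger of the strains' SDs. Genes with extra length were placed by base preference itself, so base shares are not independent of the placement.

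Single positions held more of a gene's reads in the mutant. The most used nucleotide held a median of 28 ± 9.17% of a gene's reads in the mutant and 7 ± 1.41% in wild type, each gene thinned to 50 reads (4507 genes; exact permutation p 0.2). Thinned to 20 estimated fragments, which is meant to take out most PCR copies, the values were 13.3% and 10.0% in 899 genes (permutation p 0.4). A difference in real use of single positions was therefore not detectable at this depth.

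Tested in reads, 3334 sites rose and 292121 fell relative to their gene among 426347. A simulation with no change at the libraries' fragment numbers called 863 higher and 385366 lower of 637742, so these counts are not read as changes. No site was called without wild-type replicate 1, wild-type replicate 2, mutant replicate 2 or mutant replicate 3 (edgeR; 165283, 132623, 308045 and 301483 at an unadjusted p under 0.05). Without mutant replicate 1, 13121 higher and 363088 lower were called. The sites with the largest gain by the fixed rule were in SDA1 (VII, 980638), VPS54 (IV, 495309), ARO7 (XVI, 675592), BUD8 (XII, 834925), RPL26A (XII, 819334) and BUD9 (not placed). Apart from RPL26A, each had 0 estimated fragments in mutant replicate 1, and VPS54, ARO7, BUD8 and BUD9 had at most 4 in any library. The RPL26A site, at nt 4 of the intron, had 0 fragments in both wild-type libraries and 43, 46 and 15 in the mutant libraries. The largest losses, all with 0 reads in the mutant, were at HAC1 76255, in its 3′ untranslated region (35 and 17 wild-type fragments), VMA4 943632, 24 nt before the start codon (648 and 159), SUB1 349033 (560 and 233), CDC19 73004 (258 and 106), RPL23B (771 and 118, not placed) and UBI4 (39 and 19, not placed).

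In estimated fragments, a setting chosen after the data were seen, 416 sites rose and 293 fell relative to their gene out of 24298 (edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment). The simulation without change called 0 of 28413 sites in this setting. Its libraries differed by sampling alone, so that 0 does not show how many of the 416 and 293 calls are false. At intron starts 22 of the 26 tested sites in the first 5 nt rose, in 16 genes, and 284 of 21270 placed sites elsewhere. The 5 nt were chosen after the gains were seen, and sites enter by their counts over both strains, so these proportions are not compared by a test. Besides HAC1 these included EFB1 (I, 142254, intron nt 1; 18 and 7 fragments in wild type, 39, 29 and 18 in the mutant), IWR1 (IV, 255041, nt 4; 1 and 0 against 37, 27 and 6), SRB2 (VIII, 189849, nt 2; 1 and 0 against 4, 14 and 8) and MOB2 (VI, 63972, nt 2; 3 and 1 against 7, 10 and 4), chosen after their values were seen.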

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

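Tests in this part were chosen only after the result was seen. Transcripts outside the annotated protein-coding set, which the main tests left out, held more reads in the mutant than in wild type: 1.73 ± 0.139% of all reads (SD, n = 3; 1.61, 1.70 and 1.88%) against 0.667 ± 0.000892% (SD, n = 2; exact permutation p 0.1, the smallest possible with 10 assignments). They are 687 of the profiles and stand out because a signal above the control level lies in data that the main tests did not use.

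Of the 211 with enough reads, 8 were higher and 32 lower in the mutant by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. YFL032W (117 to 4520 CPM, group means) shares 99.8% of its reads, base for base, with HAC1, so its rise is the HAC1 rise counted again. YCL041C shares 99.3% with PDI1, YOR203W 90.5% with DED1, YNL179C 89.8% with RHO5 and YDR433W 51.8% with NPL3. YDR524C-A (155 and 288 CPM in wild type, 2010, 4949 and 5583 CPM in the mutant, log2 fold change 4.30, adjusted p 0.0150), YOL013W-A (15.3 and 14.6 CPM against 110, 181 and 136 CPM, 3.30, adjusted p 0.0112) and YDR133C (63.8 and 74.9 CPM against 414, 383 and 336 CPM, 2.49, adjusted p 0.00623) shared no stretch with an annotated transcript. YFL032W and YDR524C-A together held 0.870% of mutant reads and 0.0338% of wild-type reads. No explanation was tested for the 3 without a shared stretch.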

How the results depend on the processing

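Settings built on estimated fragments, all settings for shares in introns, the distinct positions applied to lists, all transcripts and genes without extra length were chosen only after the data were seen. Among counts, shares, ratios and correlations, 157 comparisons with an alternative held, 31 moved and 3 reversed, and among base shares 62 held and 2 reversed. Among named genes 1429 comparisons held, 221 lost the call, 37 gained one and 6 reversed. Among lists 122 held and 21 lost the call, and among named sites 44 held and 59 lost it.

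Genes called higher and lower numbered 1050 and 1026 with distinct end positions (3921 tested), 1089 and 1023 in estimated fragments (3982 tested) and 1075 and 1053 with DESeq2, which kept all 498 and 432 of the edgeR calls, while coding reads alone gave 259 lower (3824 tested). Leaving out each library in turn gave 58 to 556 higher and 21 to 734 lower; where wild type was left with 1 library, the spread came from the mutant libraries and the lone library is assumed to vary like them. Sites higher numbered 649 with RLE scaling, and 416 higher and 293 lower in estimated fragments (24298 tested); with each library left out they ranged from 0 to 13121 higher and from 0 to 363088 lower. Lists called were 0 higher and 0 lower with an estimated correlation, 14 higher with distinct positions, and 8 to 10 higher and 3 to 4 lower with each library left out.

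The difference before the start codon reversed to 0.311 at 13 nt alone, over 71 genes. That of G before the end ranged from -0.486 to 0.0377 points with each library left out, the sign turning without wild-type replicate 1, and was 1.10 points with ends pooled. Spearman's rho across genes averaged 0.854 between mutant libraries and 0.755 across strains, and across sites was 0.0525 between wild-type libraries, where Pearson's r was -0.0970. Across sites, mutant replicates 2 and 3 had a rho of 0.371 and an r of 0.244. Mutant replicate 1 had a rho of 0.0872 with replicate 2 and of 0.0811 with replicate 3. The difference in ends anywhere in introns reversed to 10.97 points without RPS22B. Under distinct end positions 9 genes were called in the opposite direction, and 6 named genes reversed, HXT3 (0.38), CBP1 (-0.35), TEF4 (1.54), ILV5 (1.84), PHO84 (0.93) and PRT1 (0.059). In estimated fragments these 6 kept the direction of the reads (CBP1 0.88, adjusted p 0.0860). The cause was not tested for any of these. The replicate number as a block, over replicates 1 and 2, gave 393 genes higher and 512 lower. Same-numbered libraries deviated together with r of 0.0396 and 0.00151. Deviations of 2 wild-type libraries from their mean are mirror images, so these values do not settle whether the numbers pair the libraries. Depth limits the mutant most: its floors of 18.8 to 38.5 CPM hide falls of genes below about 26.5 CPM in wild type.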

Other observations

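The tests of the count of lower sites and of the inferred lengths of untranslated regions, and the comparison over genes that passed as observed and as drawn, were chosen only after the result was seen, as were the window of 5 nt at intron starts itself and the shares without RPS22B. Ends at the first bases of introns set the mutant apart beyond HAC1. Over 130 nuclear introns in 128 genes, HAC1 left out, 6.96 ± 0.609% of these genes' estimated fragments in the mutant (SD, n = 3; 7.62, 6.83 and 6.42%) and 0.196 ± 0.0339% in wild type (SD, n = 2) began in the first 5 nt of an intron. That is 35.4 times as much (exact permutation p 0.1, the smallest possible). Anywhere in introns the shares were 24.4 ± 6.43% and 33.5 ± 6.29% (permutation p 0.2), but the intron of RPS22B held 90.6% and 94.1% of the wild-type fragments counted there. Without RPS22B they were 14.7 ± 0.812% and 3.71 ± 0.122% (exact permutation p 0.1), and those of the first 5 nt 8.25 ± 0.190% and 0.291 ± 0.0199%. The ribosomal protein genes RPL26A and RPL28, the elongation factor gene EFB1, IWR1 and SRB2 held the most mutant fragments in the first 5 nt, and 30 introns had a larger share in every mutant library than in every wild-type library, 1 a smaller one.

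Libraries drawn from the wild-type profile with the mutants' fragment numbers reached only 3.45% of the observed share. Such a draw keeps the wild-type share on average at any depth, so it argues only against sampling scatter. Bias in capture or amplification at low depth was not tested. Reads passed between mutant replicates 2 and 3, which share 91.8% and 65.6% of each other's 1-read positions, are argued against as the whole source because without the positions read in both libraries their mean share was still 15.3 times the wild-type mean. That setting lowered their shares to 3.22% and 2.77% and the ratio over all mutant libraries to 23.1 (permutation p 0.2), so part of the size rests on positions read in both. Without the 3 introns with the most mutant ends the ratio was 30.4, so a few introns do not carry it. The difference in genotype stays open as a biological explanation and was not tested. Which enzyme makes the ends also stays open. So does whether these fragments, copied from a poly(A) tail, last longer in the mutant or are cut more often.

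Mutant ends followed the reading frame less and lacked the excess before the stop codon. Libraries drawn from the wild-type profile with the mutants' fragment numbers had 41.98% of ends at codon position 1 (3421 genes) and a ratio of 3.26 before the stop codon (1148 genes). Over genes that passed as observed and as drawn, they had 41.9% against 32.2% observed (3049 genes) and 2.73 against 0.890 (277 genes). This argues against sampling scatter from few fragments. The draw keeps the wild-type values on average at any depth, so bias in capture or amplification was not tested. In the 222 genes without extra length, where no length was inferred, codon position 1 was still lower by -6.90 points, which argues against wrong lengths of untranslated regions. The difference in genotype stays open as an untested biological explanation, and the loss of Dcp2 and that of Xrn1 cannot be separated, since no library lacks only 1 of them.

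The 292121 sites called lower in reads fit low mutant depth: with no change at all, 60.4% of 637742 simulated sites were called lower, against 68.5% of the 426347 tested. The sets of sites differ, and whether depth gives the whole count stays open. No biological reading of that count is offered, and the test in estimated fragments stands beside it. There the same simulation called 0 sites by edgeR, but its libraries differed by sampling alone, so false calls between real replicates are not bounded.

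In estimated fragments further sites rose at RPS22B 856836 (chromosome XII), inside the small nucleolar RNA gene SNR44 that its intron holds, with 1 and 7 fragments in wild type and 18, 9 and 17 in the mutant, and at RPS22B 856413, 29 nt before the start codon, with 4 and 0 against 27, 9 and 2. BDF2 331190 (chromosome IV), 167 nt into the coding sequence, had 3 and 0 against 14, 14 and 6, and the neighbouring base 331189 had 74 and 19 against 30, 25 and 10. RPP0 805836 (chromosome XII), 51 nt before the start codon, fell from 1027 and 336 fragments to 3, 2 and 0, and RPL22B 64825 (chromosome VI), 96 nt into its intron, from 296 and 115 to 0, 0 and 0. These sites were chosen after their values were seen.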
